A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

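PolyA RNA of fluazinam-treated and untreated Saccharomyces cerevisiae S288C was hybridised together on 3 two-colour arrays, with treated cDNA labelled with Cy5 and untreated cDNA with Cy3 on every array, per the labels. The series' design text calls them hybridisations of independent biological samples; whether each untreated RNA came from a culture of its own was not stated. The authors deposited 1 table of log ratios with a value per probe and array. Per the labels, spots with a flag value of 0 entered a LOWESS normalization within each array, and other probes were listed without a value. The scanner, image software, background correction, log base and direction of the ratio were not given in the sources used here. The deposited values were taken as log2 ratios of Cy5 over Cy3, that is treated over untreated. They ran from -4.48 to 5.50, so a base of 10 would put ratios beyond the range of a 16-bit scanner, which speaks against it, while a natural log cannot be ruled out and would make every fold larger. Direction was taken from the channel order and the usual convention, and turning it would turn every sign.

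Array medians were 0.09, -0.02 and 0.01 for replicates 1 to 3, and SDs of the values were 1.01, 0.80 and 0.90. A value was present for 71.2%, 83.6% and 77.6% of the 6272 probes; 3877 probes had a value on all 3 arrays, 1192 on 2, 558 on 1 and 645 on none. A spot can lack a value because it was flagged, and why spots were flagged was not stated. Array depth in the sense of signal over background was unknown without intensities.

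Probes were named through a platform annotation table: 5308 had 1 gene symbol, 0 had several and 964 had none. Of the named probes, 5304 matched a gene of the reference gene table (assembly R64) by Entrez identifier, 4 did not, and no symbol changed. The reference gave names and locus tags only, since the build behind the array was not named, so no coordinates are given. The named probes stood for 5203 genes, and the 88 genes with more than 1 probe were averaged per array. Probe sequences were not used here, so transcripts of near-identical gene copies, which many ribosomal protein genes have, may share signal on a probe.

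Genes and unnamed features with a value on all 3 arrays were tested, 3802 in all, 3574 of them named. The mean log2 ratio was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intercept only, and p-values were adjusted by Benjamini and Hochberg's method over all features, with a threshold of 0.05. The moderation had 5.10 prior degrees of freedom. SDs are over the 3 arrays. Data for this comparison were simulated 20 times, with 3802 genes of which 200 were changed. The test recovered 11.8% of genes changed by a log2 of 1, 85.7% of those changed by 2 and 98.6% of those changed by 3. Of its calls, 6.19% were false. The simulated noise was independent between genes, with no effect of position and no array that stood apart. The share of false calls among the real ones is therefore not known from it.

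Before the data were examined, 43 gene lists were fixed from textbook knowledge of yeast pathways and of the compound's class. For each, members past the threshold were counted over all features and adjusted over the list alone. The 38 lists with at least 5 measured members were compared with all other genes by limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with a correlation estimated for each list and fry were run beside it. In simulated data, camera recovered 100% of lists shifted by a log2 of 1 and called 0.05 unshifted lists per simulation; those simulations held no correlation between genes, so they do not bear on the estimated one. Members were matched by symbol, and by a synonym only where no gene of the reference table has it as its own symbol. Only 1 measured gene, HSP12, stood in more than 1 list.

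The named genes follow a rule fixed at the same time: the 12 largest rises and 12 largest falls past the threshold with 1 sign on all arrays, up to 4 members of each list past the threshold or otherwise the member with the largest mean, and PDR5, SNQ2, YOR1, PMA1, CIT2, HSP12, HSP104 and CTT1 whatever their values.

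Alternatives were centring on the array median, a common median absolute deviation, genes with values on at least 2 arrays, robust moderation, array weights, quantile normalization, leaving out each array, no moderation, an adjusted p under 0.01, a test against a 1.5-fold change, the first listed probe of a gene, and for lists an estimated correlation, ranks and leaving out the shared gene. Robust moderation and values on at least 2 arrays used camera's version for precomputed statistics. The probe numbers appear to give a sub-grid column, a sub-grid row and a place among 14 by 14 spots, which makes 32 sub-grids in 4 columns and 8 rows; this layout was inferred, not stated. Subtracting each sub-grid's median per array, alone and with replicate 1 left out, was added after seeing the data.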

Results

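Transcript levels were compared between yeast cells treated with fluazinam and untreated cells. Fluazinam is an agricultural fungicide of the dinitroaniline class, a weak acid known as an uncoupler of oxidative phosphorylation. Saccharomyces cerevisiae S288C, the standard laboratory strain, was grown in rich glucose medium (YPD) at 25 C, and exponentially growing 100 ml cultures were exposed to 1.5 uM fluazinam for 2 h. The data comprised 3 two-colour arrays, described by the labels as independent biological samples, each with Cy5-labelled cDNA of treated cells and Cy3-labelled cDNA of untreated cells. No dyes were swapped, so a dye effect specific to a gene could not be separated from the treatment. Of 6272 probes, 4463 had a value on replicate 1, 5245 on replicate 2 and 4865 on replicate 3, and 3802 genes or unnamed features with a value on all 3 arrays were tested. The number of arrays and the spread between them limit the precision. What spot intensities would add was unknown, as none were given.

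The values were signed log ratios whose base and direction were not stated, and they were read as log2 of treated over untreated. The direction is likely rather than settled: it rests on the treated sample being channel 1 and Cy5, and with the opposite sign every rise below would be a fall. Across the tested features, the Pearson correlation was 0.507 between replicates 1 and 2, 0.629 between replicates 1 and 3 and 0.434 between replicates 2 and 3, taken across genes, which are not independent replicates. All 3 arrays gave 1 sign for 52.3% of the features, where chance gives 25%.

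The comparison of treated with untreated cells asks which transcripts fluazinam changed after 2 h. The largest rises were those of FIT2 (YOR382W), a cell wall mannoprotein that retains siderophore-bound iron, at a log2 ratio of 3.74 ± 0.82 (SD, n = 3), and HSP26 (YBR072W), a small heat shock protein, at 3.73 ± 1.63. The largest falls were those of URA7 (YBL039C), a CTP synthase, at -2.85 ± 1.42, and RPS10A (YOR293W), a protein of the small ribosomal subunit, at -2.72 ± 1.06. General stress genes, stationary phase markers and genes of iron uptake were higher in treated cells, and genes for ribosomal proteins, ribosome assembly and purine synthesis were lower. These 6 lists passed a set test with a preset correlation, and none did with an estimated one (adjusted p = 0.521 to adjusted p = 0.570 with an estimated correlation). With 3 arrays the test with an estimated correlation has 2 degrees of freedom. A list can hardly pass it, so its failure here and below decides little. In all, 299 features passed the threshold, 129 higher and 170 lower, each with 1 sign on all 3 arrays and a mean change of at least 2-fold.

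Further large rises were those of GPG1 (3.21 ± 0.63), MOH1 (3.07 ± 0.79), HSP12 (2.96 ± 0.54), TFS1 (2.87 ± 1.44) and BDH2 (2.86 ± 0.97). HSP12 encodes a membrane-associated stress protein and TFS1 an inhibitor of carboxypeptidase Y. VBA5 rose by 2.72 ± 1.49, PHM7 by 2.68 ± 0.75, the transaldolase paralogue NQM1 by 2.65 ± 0.88 and FMP16 by 2.49 ± 1.16. The trans-aconitate methyltransferase gene TMT1 rose by 2.60 ± 1.73, with 1.87, 4.57 and 1.35 on replicates 1 to 3. Among the falls, RPL11A (-2.42 ± 1.27), RPS20 (-2.39 ± 1.21), RPS4B (-2.35 ± 0.93) and RPS15 (-2.31 ± 0.66) encode ribosomal proteins. NOP1 (-2.38 ± 0.50), GAR1 (-2.19 ± 0.30) and NOP56 (-2.18 ± 1.10) encode core proteins of small nucleolar ribonucleoproteins, and RPA49 (-2.31 ± 1.15) a subunit of RNA polymerase I. SHM2 (-2.37 ± 0.73), the cytosolic serine hydroxymethyltransferase, and ADE13 (-2.26 ± 1.06), the adenylosuccinate lyase of purine synthesis, completed the 12 largest falls. Of 18 unnamed probes past the threshold, 3 were higher, among them probe 3010804 (3.68 ± 0.81), and 15 were lower, among them probe 3080509 (-2.63 ± 0.68).

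**Figure D1:**
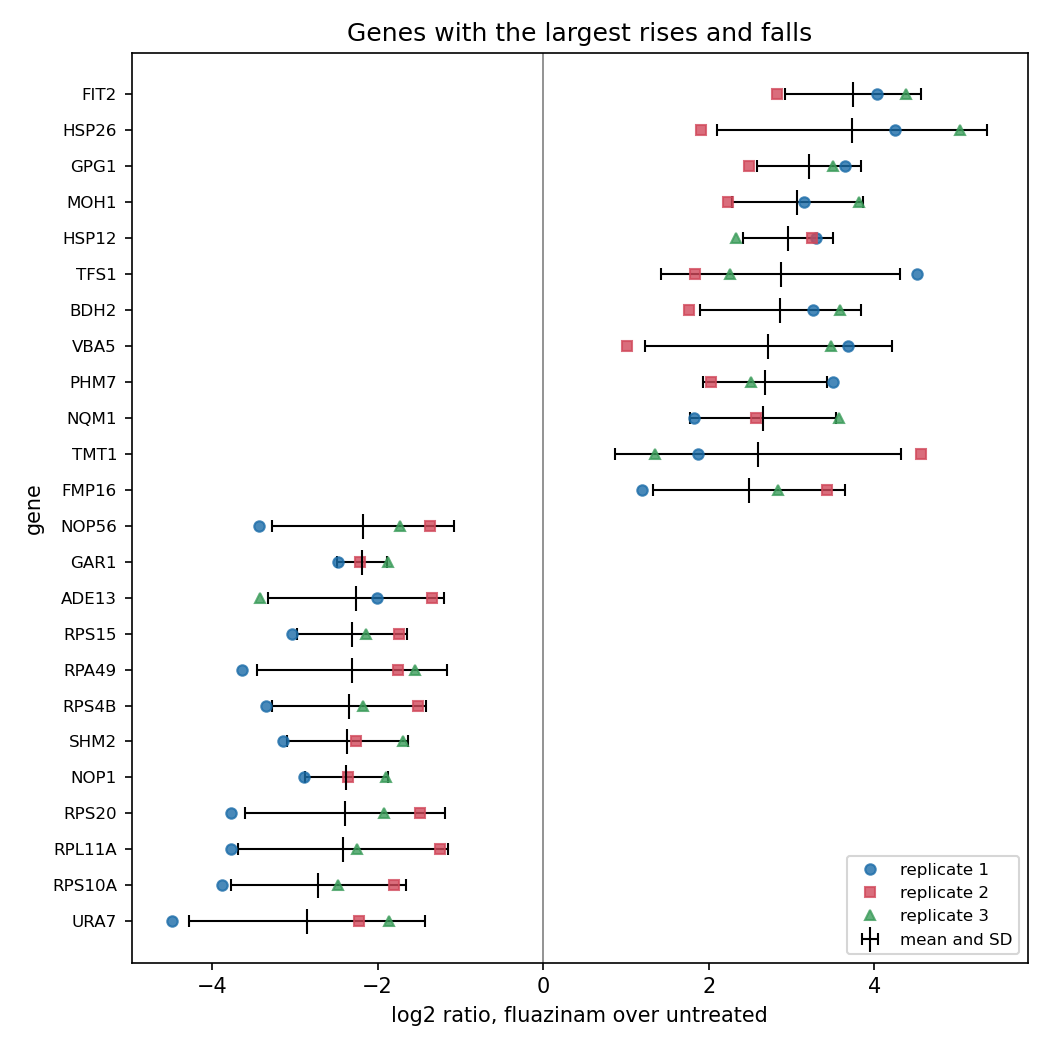
Log2 ratio of fluazinam-treated over untreated cells (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls (vertical axis); coloured symbols are the 3 arrays, and black marks are the mean with the SD. Every array lies on the same side of 0 for each gene, as the rule that chose the genes required. The mean runs from 3.74 for FIT2 to -2.85 for URA7.

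The limma test with Benjamini-Hochberg adjustment gave a smallest adjusted p of 0.0206, so no feature passed at 0.01, and 1129 features had an unadjusted p under 0.05. The count depended on which arrays were used: without replicate 1 it was 11 and without replicate 3 it was 0, with 878 features at an unadjusted p under 0.05, while without replicate 2 it was 657, 283 of them among the 299. Of the members of all lists, 83 passed. Without replicate 1 only HSP12 and FIT2 did, without replicate 2 it was 236 and without replicate 3 it was 0. With all arrays but no moderation, 1 feature passed, and it was not among the 299.

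General stress genes of the Msn2/Msn4 type, which many stresses induce together, were higher as a group. Of 17 measured, 10 rose and 7 did not pass the test, and 16 rose when adjusted over the list alone. Besides HSP12 and TFS1, GLK1 (2.36 ± 1.00), a glucokinase, and MSC1 (2.28 ± 0.60) rose. The list's median was 1.51, with array medians of 2.09, 1.24 and 1.71, and it shifted against all other genes (camera adjusted p = 6.29e-11; adjusted p = 0.521 with an estimated correlation). Stationary phase markers had a median of 2.03 over 6 measured genes, and HSP12, SPG4 (1.81 ± 0.64) and the polyubiquitin gene UBI4 (1.58 ± 0.16) rose, with 5 rising when adjusted over the list alone (camera adjusted p = 5.86e-04; adjusted p = 0.521 with an estimated correlation). Array medians were 1.58, 2.89 and 1.22, and without replicate 2 the median was 1.36. The other members, outside the rule for named genes, did not pass over all features. They were SNZ1 (2.52 ± 2.19, adjusted p = 0.0743), SNO1 (2.26 ± 2.13, 0.0892) and SPG5 (0.04 ± 0.79, 0.944). HSP12 stands in both lists.

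Heat shock proteins and chaperones had a median of 0.38 over 25 measured genes, of which HSP26 alone rose, also when adjusted over the list alone. Array medians were 0.64, 0.14 and 0.59. The shift passed the set test (adjusted p = 0.0174; adjusted p = 0.638 with an estimated correlation), but not without replicate 1 (0.0617), and the median was 0.24 to 0.61 over the arrays left out. HSP104, the disaggregase, was at 0.77 ± 0.28 (adjusted p = 0.108) and CTT1, the cytosolic catalase, at 0.20 ± 0.92 (0.754), and neither passed. Trehalose and glycogen genes had a median of 0.51 over 16 measured (array medians 0.37, -0.02 and 1.10). GPH1 (2.14 ± 1.42), the glycogen phosphorylase, and NTH1 (1.23 ± 0.19), a trehalase, rose, and both encode enzymes that break down these reserves. The list also holds genes of their synthesis. Of the 16, 15 had a mean above 0 and 5 were above 0 on all 3 arrays. With 4 members rising when adjusted over the list alone, the list passed at 0.0049 (adjusted p = 0.688 with an estimated correlation), and not without replicate 3 (0.153), where the median was 0.32; without replicate 2 it was 0.84.

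Genes of protein synthesis were lower. All 115 measured cytosolic ribosomal protein genes had a mean below 0; 23 fell, and 84 fell when adjusted over the list alone. The list's median was -1.24, with array medians of -2.06, -0.31 and -1.22, so the shift on replicate 2 was the smallest (camera adjusted p = 2.86e-24; adjusted p = 0.570 with an estimated correlation). The count of 23 became 0 without replicate 1, 104 without replicate 2 and 0 without replicate 3, with medians of -0.80, -1.71 and -1.25. Of 45 measured ribosome biogenesis genes, 13 fell and 28 fell when adjusted over the list alone, NOP1, GAR1, NOP56 and NOP58 (-2.12 ± 0.67) by the most. Their median was -0.86, with array medians of -1.12, -0.73 and -0.87 (camera adjusted p = 1.60e-10; adjusted p = 0.521 with an estimated correlation). Of 16 measured genes of RNA polymerases I and III, RPA49 and RPA190 (-1.64 ± 0.87) fell and 5 fell when adjusted over the list alone; the median was -0.56, with array medians of -0.83, -0.39 and -0.68 (camera adjusted p = 0.00210; adjusted p = 0.521 with an estimated correlation).

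Purine biosynthesis genes had a median of -1.23 over 11 measured, all with a mean below 0. ADE13, ADE2 (-2.18 ± 0.59), ADE4 (-2.11 ± 0.92) and the IMP dehydrogenase gene IMD3 (-2.02 ± 0.78) were among the 6 that fell, and 9 fell when adjusted over the list alone. Array medians were -1.51, -1.07 and -1.40 (camera adjusted p = 2.35e-06; adjusted p = 0.570 with an estimated correlation).

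The iron regulon, the genes induced when iron is scarce, had a median of 1.05 over 16 measured genes. FIT2, the siderophore transporter gene ENB1 (2.10 ± 0.95) and FIT3 (2.06 ± 1.06) rose, while FRE1 (-1.37 ± 0.22), a cell surface ferric and cupric reductase, fell; adjusted over the list alone, 9 rose and 1 fell. Array medians were 1.65, 0.21 and 1.15, and leaving out 1 array gave medians of 0.65 to 1.47 (camera adjusted p = 2.83e-04; adjusted p = 0.570 with an estimated correlation).

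Weak organic acid response genes had a median of 0.73 over 8 measured, with array medians of 0.59, 0.90 and 1.39. YRO2 (2.34 ± 0.40), ATO2 (1.55 ± 0.70) and the polyamine transporter gene TPO2 (1.49 ± 0.29) rose, also when adjusted over the list alone (camera adjusted p = 0.00215; adjusted p = 0.521 with an estimated correlation). Targets of Pdr1 and Pdr3, the regulators of multidrug resistance, had a median of 0.77 over 8 measured, and none passed, nor any when adjusted over the list alone. The list passed the set test (camera adjusted p = 0.0266, and adjusted p = 0.688 with an estimated correlation). Array medians were 1.37, -0.12 and 0.66, and medians were 0.47 to 1.02 over the arrays left out. It did not pass without replicate 1 (0.114) or replicate 3 (0.0793). Without replicate 2 it passed at 1.35e-04, and 4 of the 8 members rose. PDR5, the main drug efflux pump gene, had log2 ratios of 2.87, -0.57 and 3.59 on the 3 arrays (mean 1.96 ± 2.22, adjusted p = 0.125), and YOR1, another efflux pump gene, was at 0.55 ± 0.35 (0.231). SNQ2 was not analysed here. Aryl-alcohol dehydrogenase genes had a median of 0.79 over 5 measured; AAD10 (1.70 ± 0.63) rose, and 2 rose when adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.570 with an estimated correlation). Array medians were 1.60, 0.25 and 0.75, and without replicate 1 the median was 0.40 and no member passed. The estimated correlation of these 5 genes was 0.668, far above the preset 0.01, so they are not close to independent.

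Several lists of carbon and nitrogen metabolism were higher by the genes measured on all 3 arrays. These were 5 of 13 beta-oxidation genes on the array, 8 of 13 hexose transporters and 5 of 12 gluconeogenesis and glyoxylate cycle genes. For nitrogen catabolite repression they were 9 of 19. The medians therefore do not stand for the whole lists. Fatty acid beta-oxidation genes had a median of 0.84 over 5 measured, and CRC1 (1.88 ± 0.32), the mitochondrial carnitine carrier, and POT1 (1.59 ± 0.62), the peroxisomal thiolase, rose, also when adjusted over the list alone (camera adjusted p = 0.00615; adjusted p = 0.521 with an estimated correlation). Array medians were 0.89, 0.87 and 1.66, and the median was 0.54 to 1.12 over the arrays left out. Hexose transporters had a median of 0.69 over 8 measured (array medians 0.75, 0.26 and 1.32), of which HXT5 (1.62 ± 0.66) rose, also when adjusted over the list alone (camera adjusted p = 0.0105, and 0.0702 without replicate 3; adjusted p = 0.570 with an estimated correlation). Their median was 1.20 with 4 rises without replicate 2, and 0.39 with 0 rises without replicate 3. Gluconeogenesis and glyoxylate cycle genes had a median of 0.74 over 5 measured (array medians 0.83, 0.23 and 0.79) and none passed, while 2 passed upward when adjusted over the list alone. The set test gave an adjusted p of 0.0247 (adjusted p = 0.570 with an estimated correlation), 0.0511 without replicate 1 and 0.0793 without replicate 3, and the median was 0.37 to 1.13 over the arrays left out; MDH2, the cytosolic malate dehydrogenase, was at 1.20 ± 0.53 (0.0563). Genes under nitrogen catabolite repression had a median of 0.77 over 9 measured (array medians 0.66, 0.72 and 0.83), with rises of UGA1 (1.29 ± 0.50) and the general amino acid permease gene GAP1 (1.26 ± 0.28), and 5 rose when adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.521 with an estimated correlation). That list lost its call without replicate 2 (0.0618), where its median was 0.67. It was the only list that passed fry, a rotation test of whether a list's genes move 1 way (adjusted p = 0.0149). Phosphate regulon genes had a median of -0.47 over 14 measured (array medians -0.11, -1.15 and -0.17, and -0.79 to -0.25 over the arrays left out), none past the threshold and none when adjusted over the list alone (camera adjusted p = 0.0393, and 0.443 without replicate 2; adjusted p = 0.570 with an estimated correlation). The polyphosphate synthesis gene VTC2 was at -1.07 ± 0.53 (0.0718).

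**Figure D2:**
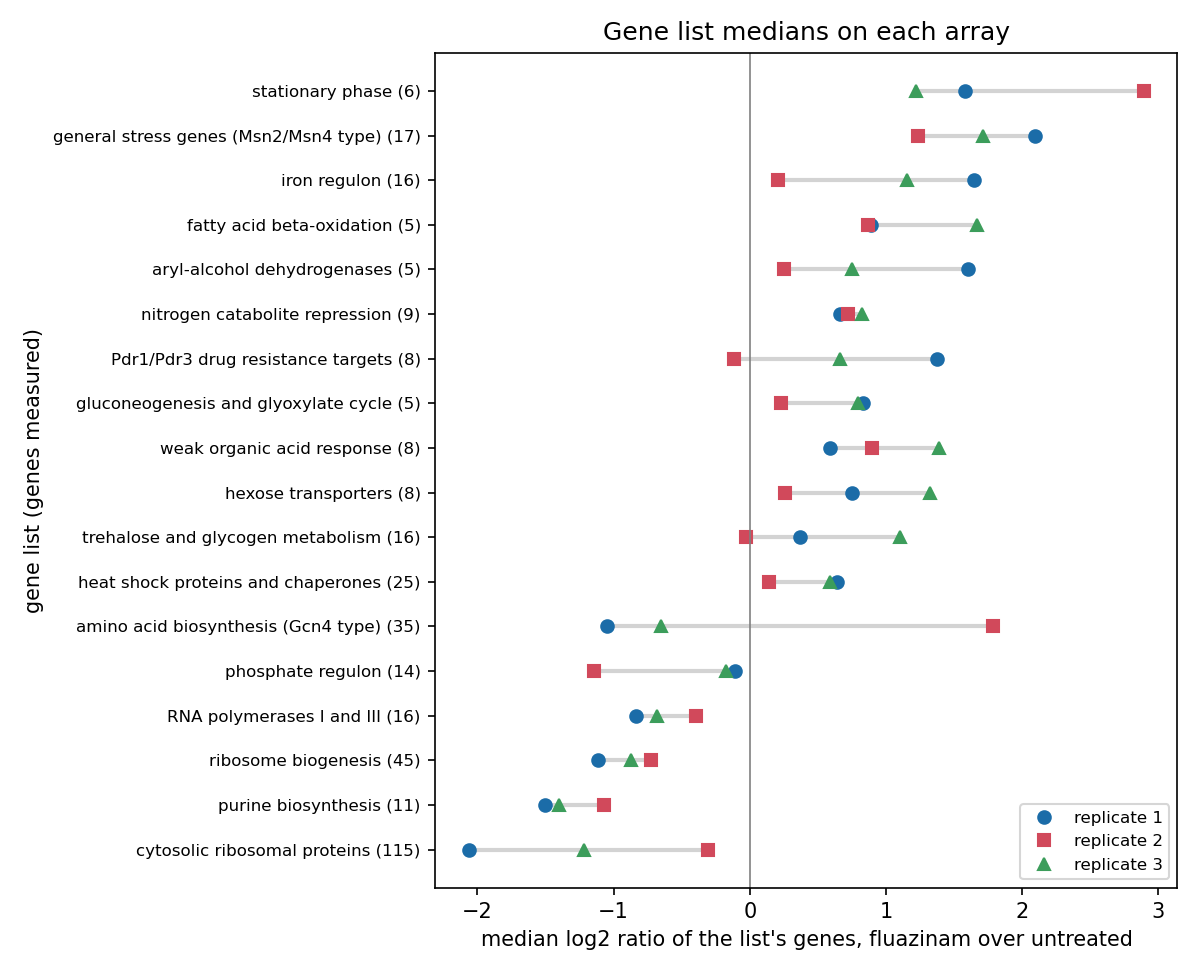
Median log2 ratio of treated over untreated cells (horizontal axis) on each of the 3 arrays for the 17 gene lists past the set test and for amino acid biosynthesis (vertical axis, with the number of genes measured). General stress genes lie between 1.24 and 2.09 on all arrays, while amino acid biosynthesis genes lie at 1.79 on replicate 2 and at -1.05 and -0.65 on the others.

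The 35 measured amino acid biosynthesis genes, the classical targets of the transcription factor Gcn4, had array medians of -1.05, 1.79 and -0.65. The list did not pass (median 0.10, camera adjusted p = 0.501), and LEU2 (1.90 ± 0.28), an enzyme gene of leucine synthesis, was the only member to rise, also when adjusted over the list alone. Without replicate 1 the list passed upward at 0.00111 and without replicate 3 at 0.0489, and without replicate 2 it passed downward with a median of -0.88 (adjusted p = 1.35e-04). With all arrays it had adjusted p = 0.935 with an estimated correlation, which at 0.921 was the highest of any list. Sulfur amino acid genes had a median of 0.40 over 18 measured and did not pass (0.0806), but passed upward without replicate 1 (0.0282) and without replicate 3 (0.0396), and not without replicate 2, where the median was 0.21 (0.237). With all arrays the list had adjusted p = 0.570 with an estimated correlation. MET17 (2.02 ± 0.89) and MET13 (1.48 ± 0.75) rose, and adjusted over the list alone 4 rose and 1 fell.

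Energy metabolism lists did not pass the set test with all arrays. The median was 0.17 for 15 tricarboxylic acid cycle genes (adjusted p = 0.390), -0.31 for 17 nuclear-encoded respiratory chain genes (0.360), 0.13 for 12 ATP synthase genes (0.688), 0.03 for 43 mitochondrial ribosomal protein genes (0.754), -0.23 for 15 mitochondrial import genes (0.360) and -0.21 for 17 glycolytic genes (0.754). CYT1 (-1.89 ± 0.92), cytochrome c1, fell, also when adjusted over the list alone, and without replicate 2 the respiratory chain list passed downward with a median of -0.61 (adjusted p = 0.0470), while without replicate 3 the median was -0.01 (0.668). With all arrays that list had adjusted p = 0.818 with an estimated correlation. Over the arrays left out the medians were 0.15 to 0.35 for the tricarboxylic acid cycle, -0.05 to 0.16 for ATP synthase, -0.08 to 0.12 for mitochondrial ribosomal proteins, -0.43 to -0.04 for import and -0.21 to -0.16 for glycolysis. In the same order, array medians were 0.17, 0.03 and 0.45, then -0.13, 0.36 and 0.06, then 0.27, -0.34 and 0.18, then 0.19, -0.62 and -0.26, and 0.24, -0.60 and 0.20. Except for the tricarboxylic acid cycle, the arrays thus differed in sign. No gene of the other 5 lists passed, nor did any when adjusted over the list alone; the members farthest from 0 were SDH2 (-0.84 ± 0.99), ATP14 (-0.52 ± 0.55), MRPL6 (-0.93 ± 1.26), TIM23 (-0.84 ± 1.53) and PDC5 (-1.20 ± 0.74). The list for the retrograde response to mitochondrial dysfunction held 7 measured genes. They include its regulators RTG1, RTG2, RTG3 and MKS1, so the list's median is not that of induced genes alone. It was 0.57 (0.113), and the list passed upward without replicate 1 at 0.75 (0.0403). Without replicate 2 it did not pass, at 0.21 (0.364). That list had adjusted p = 0.570 with an estimated correlation and all arrays; CIT2 (1.69 ± 0.28), the peroxisomal citrate synthase and the usual marker of that response, rose, and 2 rose when adjusted over the list alone. Proton pump genes had a median of -0.16 over 16 measured (0.391; -0.29 to 0.04 over the arrays left out), where HSP30 (1.96 ± 1.06), a plasma membrane stress protein that restrains the proton pump, rose, also when adjusted over the list alone. PMA1, the plasma membrane proton pump itself, was at -0.44 ± 0.21 (0.296).

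Among the other stress, membrane and wall lists, none passed. Medians were 0.27 for 24 oxidative stress and glutathione genes (adjusted p = 0.176), 0.14 for 34 proteasome genes (0.334), -0.16 for 13 unfolded protein response genes (0.391), 0.15 for 17 cell wall genes (0.391), -0.30 for 21 ergosterol genes (0.113) and -0.19 for 12 fatty acid and phospholipid genes (0.540). In the same order, the medians over the arrays left out were 0.21 to 0.41, 0.02 to 0.15, -0.32 to 0.09, -0.11 to 0.28, -0.39 to -0.15 and -0.37 to 0.02. The glutathione transferase gene GTT1 (2.06 ± 1.01), the glucan synthase gene GSC2 (1.67 ± 0.28) and the wall protein gene SED1 (1.34 ± 0.49) rose. PDI1 (-1.36 ± 0.47), protein disulfide isomerase, and PIS1 (-1.18 ± 0.32), phosphatidylinositol synthase, fell. Adjusted over the list alone, 1 oxidative stress gene and 3 cell wall genes rose, 1 cell wall gene, 2 unfolded protein response genes and 2 fatty acid and phospholipid genes fell, and no proteasome or ergosterol gene passed. PRE8 (0.99 ± 0.85) and ERG7 (-1.42 ± 0.95) were the members of those last lists farthest from 0.

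Thiamine genes had a median of 0.10 over 7 measured (adjusted p = 0.390), hypoxic and haem-repressed genes -0.11 over 9 (0.391), core histones -0.44 over 7 (0.309) and G1/S cell cycle genes -0.34 over 9 (0.310). Daughter-specific early G1 genes had a median of -0.06 and a mean of 0.04 over 11 (0.916), so median and test differed in sign. In the same order, the medians over the arrays left out were -0.21 to 0.41, -0.25 to -0.03, -0.65 to -0.02, -0.64 to -0.05 and -0.23 to 0.26. No member of these 5 lists passed; THI13 was at 1.37 ± 0.73, ANB1 at -1.03 ± 0.40, HTB2 at -0.78 ± 0.28, RNR1 at -1.30 ± 0.67 and DSE4 at 1.07 ± 1.27. Adjusted over the list alone, 1 thiamine gene rose and 1 G1/S gene fell. Fewer than 5 genes were measured on all 3 arrays for the remaining lists, which therefore had no set test, and no member was past the threshold. The 3 DNA damage genes had a median of -0.06, or -0.93 to 0.12 over the arrays left out (RNR4 at -0.76 ± 0.64), the 3 G2/M genes -0.78 (CLB1 at -0.996 ± 0.548) and the 3 meiosis and sporulation genes 0.45 (NDT80 at 0.59 ± 0.64). The 3 markers of mating type alpha had a median of -1.05 (MF(ALPHA)2 at -1.11 ± 0.92), and STE6, the 1 measured marker of mating type a, was at 0.76 ± 0.38. Adjusted over the list alone, which adjusts little in lists of at most 3 genes, all 3 alpha markers and 1 G2/M gene passed downward and STE6 upward. No DNA damage or meiosis gene passed. For STE6, alone in its list, that is the unadjusted p, and its limma adjusted p over all features was 0.119. Of all 3802 features, 1129 had an unadjusted p under 0.05, so such passes are common. With values on at least 2 arrays, 9 G2/M genes were measured, and the list passed downward with a median of -0.59 (camera adjusted p = 0.0469). The DNA damage (0.835) and meiosis (0.214) lists did not pass. These tests used the preset correlation, and none with an estimated correlation was run for these lists. With sub-grid medians subtracted, CLB1 (-1.17 ± 0.53, adjusted p = 0.0444) and MF(ALPHA)2 (-1.29 ± 0.74, 0.0487) passed, and 1 hypoxic and haem-repressed gene fell.

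In total, 17 of 38 lists tested passed with the preset correlation, 12 higher and 5 lower, and 0 passed with an estimated correlation, where limma's camera has 2 degrees of freedom, the smallest unadjusted p was 0.0588 and fry passed 1 list. Position also carried a difference: on replicate 1 the median by sub-grid row ran from 0.35 in row 1 to -0.84 in row 8. Replicate 2 ran from 0.04 in row 1 to -0.50 in row 8, and replicate 3 from 0.18 in row 2 to -0.46 in row 6. With sub-grid medians subtracted, a setting chosen after seeing the data, 391 features passed, 250 of them among the 299. That setting ended the calls of 6 named genes, whose means moved towards 0: PIS1 from -1.18 ± 0.32 to -0.62 ± 0.33 (adjusted p = 0.127), PDI1 from -1.36 ± 0.47 to -0.93 ± 0.52 (0.0701), RPL11A from -2.42 ± 1.27 to -1.86 ± 1.31 (0.0514), GPH1 from 2.14 ± 1.42 to 1.82 ± 1.33 (0.0556), TMT1 from 2.60 ± 1.73 to 2.40 ± 1.82 (0.0536) and MET13 from 1.48 ± 0.75 to 1.39 ± 0.88 (0.0526).

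**Figure D3:**
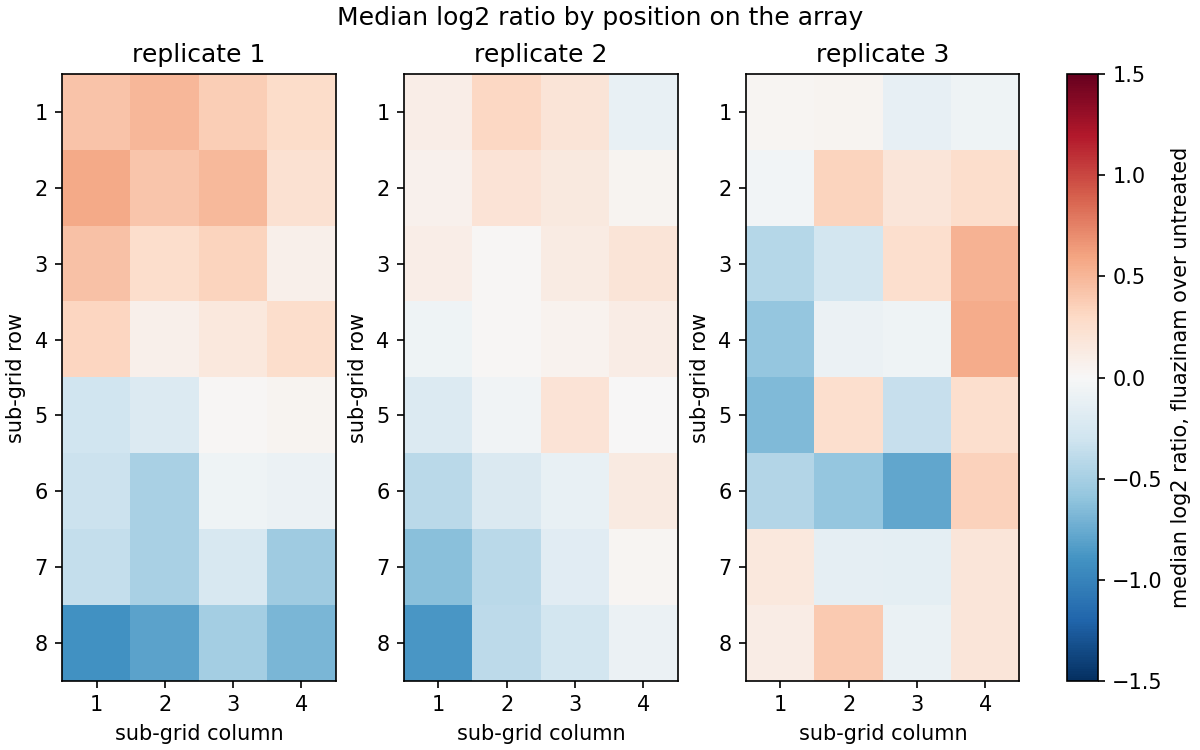
Median log2 ratio of treated over untreated cells (colour) in each of the 32 sub-grids of the array, by sub-grid column (horizontal axis) and row (vertical axis), for the 3 arrays; the layout was read from the probe numbers. On replicate 1 the ratios are above 0 in the first rows and below 0 in the last ones. Replicate 2 has a smaller fall along the rows in columns 1 to 3, but not in column 4. On replicate 3 the columns differ, and in row 6 the median is -0.78 in column 3 and 0.34 in column 4.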

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

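Subtracting sub-grid medians, with or without replicate 1, was chosen after seeing the data; the other settings were planned. Leaving out 1 array gave 0 to 657 features, 0 to 278 of them higher and 0 to 379 lower, with 0 to 657 changed at least 2-fold: 11 without replicate 1, 657 without replicate 2 and 0 without replicate 3, where limma gave 720, 1085 and 878 at an unadjusted p under 0.05. These fits had fewer arrays. Their prior degrees of freedom were 7.30, 21.7 and 6.07 in that order, so the moderation was strongest without replicate 2. The 657 features there came with 1085 at an unadjusted p under 0.05, against 1129 with all arrays. That count alone therefore does not show a stronger response. What else made the fits differ was not tested. No moderation gave 1 feature (1 higher, 0 lower, 0 at least 2-fold), with 609 at an unadjusted p under 0.05. That feature was not among the 299, so each of the 299 calls rests on the moderation. An adjusted p under 0.01 gave 0 in every count, where 1129 had an unadjusted p under 0.05, and a test against 1.5-fold gave 4 (4 higher, 0 lower, 4 at least 2-fold), as stricter tests. The remaining settings gave 239 to 424 features, all within 1.5 times of 299; the 424 of quantile normalization and the 399 of robust moderation held all 299. Of 82 named genes tested, 58 passed, and of these 52 lost their call without replicate 1, 58 without replicate 3, 4 without replicate 2 and 6 with sub-grid medians subtracted. With values on at least 2 arrays, which adjusts over more features, GPH1, MET13, PIS1, RPA190, TMT1 and UGA1 lost it with unchanged means, and with a common median absolute deviation TMT1 did; centring, robust moderation, array weights and quantile normalization ended none. With an estimated correlation 0 lists passed, where camera has 2 degrees of freedom. For the 17 lists the estimates ran from -0.114 for nitrogen catabolite repression to 0.864 for ribosomal proteins. Those of beta-oxidation (-0.034), weak acid response (-0.030) and RNA polymerases I and III (-0.0099) were also below the preset 0.01. These lists and nitrogen catabolite repression still did not pass, so a higher correlation was not what ended their calls. The other 13 settings run for lists all kept the preset correlation of 0.01, so they do not bear on that choice. In these, 10 of the 17 passed each time: ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, purine biosynthesis, general stress, stationary phase, the iron regulon, weak acid response, beta-oxidation and aryl-alcohol dehydrogenases. Amino acid biosynthesis turned direction without replicate 2, its median ranging from -0.88 to 0.73 over the arrays left out; replicate 2 alone held the opposite sign. With sub-grid medians subtracted 18 lists passed, oxidative stress, proteasome and ergosterol genes among them (adjusted p = 0.570, 0.771 and 0.570 with an estimated correlation before subtraction). Gluconeogenesis and phosphate genes no longer passed: their mean against all other genes moved towards 0, from 0.79 to 0.59 (SD over genes 0.38 and 0.40, adjusted p = 0.0557) and from -0.47 to -0.38 (SD 0.36 and 0.36, adjusted p = 0.103). The phosphate median moved away from 0, from -0.47 to -0.52. With replicate 1 left out as well 19 lists passed, 15 of them among the 17. Amino acid, sulfur amino acid, ergosterol and G1/S genes were gained there, and Pdr1/Pdr3 and gluconeogenesis genes were lost. With values on at least 2 arrays the phosphate list also lost its call, and the G2/M list, tested only there, passed. Each ratio already pairs treated with untreated RNA of 1 array, so no further block was fitted. The number of arrays and the spread between them limit precision, and what signal over background adds was unknown.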

Other observations

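Genes outside the fixed lists were grouped by the letters of their names into 77 families with at least 5 measured members, a grouping chosen after seeing the data. Autophagy genes (ATG) were higher, with a median log2 ratio of 0.77 over 20 measured genes and array medians of 0.64, 0.83 and 0.99. Of these, 5 rose: ATG33 (1.97 ± 0.21), ATG22 (1.85 ± 0.72), ATG39 (1.72 ± 0.37), ATG8 (1.50 ± 0.60), the ubiquitin-like protein of the autophagosome membrane, and ATG9 (1.07 ± 0.08). The family passed camera with an adjusted p of 5.27e-05, and the smallest adjusted p = 0.817 with an estimated correlation for any family. Translation initiation factor genes (TIF) had a median of -1.06 over 7 measured, and TIF34 (-1.60 ± 0.10), TIF1 (-1.46 ± 0.52) and TIF5 (-1.24 ± 0.39) fell (camera adjusted p = 0.00274; adjusted p = 0.817 with an estimated correlation). Genes named FMP, for proteins found in mitochondria, had a median of 0.64 over 11 measured with 5 rises, and nucleoporin genes (NUP) a median of -0.51 over 16 measured with falls of NUP82 (-1.37 ± 0.61) and NUP145 (-1.19 ± 0.36). Their camera adjusted p was 0.0111 and 0.0290 (adjusted p = 0.817 with an estimated correlation for both).

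All tests below except that of array position for the ribosomal protein and biogenesis genes together were chosen only after the result was seen. The limits of the position and dye tests for these genes were also changed afterwards. For position the limit of -0.3 on each array became 0; the earlier limit was met by the median of both lists together, though its interval reached -0.28 on replicate 2, but not by ribosomal proteins alone on replicate 2. For the dye test the limit was moved from the mean to each array, which left open an explanation that the mean had counted against.

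Amino acid biosynthesis genes stood apart on replicate 2, with the largest gap of the 38 lists: all 35 measured were highest there, as were 30.7% of all features, and 23 were above 0 on that array and below 0 on the others. Exchanged channels on replicate 2 would have put the general stress genes below 0, and their median there was 1.24; position on the array would have left little gap after subtracting sub-grid medians, and the gap was 2.52. A weaker form of the same response would keep the sign of replicates 1 and 3, and the list's median on replicate 2 was 1.79, with 34 of 35 genes above 0. For the other 37 lists, Pearson's r across lists between replicate 2 and the mean of the others was 0.620, with a slope of 0.596. Over all 38 lists the slope was 0.483, against 0.918 for replicate 1 and 0.902 for replicate 3. The mean absolute list median was nearer, at 0.551 on replicate 2 and 0.623 for the mean of the others. A weaker response there stays open. A different amino acid supply in 1 of the 2 cultures behind that array may be a candidate explanation, but the design names no such difference and no biological explanation was tested.

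The lower ratios of ribosomal protein and biogenesis genes could reflect their place on the array or their brightness. With sub-grid medians subtracted, the median was -1.28 for ribosomal proteins, with 30 falls (camera adjusted p = 1.36e-23; adjusted p = 0.570 with an estimated correlation before subtraction), and -1.01 for biogenesis genes, with 15 falls. Against unlisted genes of the same sub-grid, ribosomal proteins lay at -2.17, -0.25 and -1.17 on the 3 arrays. Biogenesis genes lay at -1.42, -0.69 and -0.90, and both together at -2.10, -0.39 and -1.13. Every median was below 0 on every array, which argues against sub-grid position as the whole cause. Every 95% bootstrap interval over genes was also below 0, and on replicate 2 the ribosomal protein interval was -0.35 to -0.18. The bootstrap took genes as independent, while ribosomal proteins had an estimated correlation of 0.864. Its intervals are therefore too narrow, and they do not measure the spread between arrays. Ribosomal protein genes lay below glycolytic genes, which are also abundant, by a median difference of -1.04, with -2.30, 0.29 and -1.42 per array, and biogenesis genes differed from glycolytic genes by -1.36, -0.13 and -1.07. A dye effect at bright spots cannot be told apart from the treatment, because replicate 2 shows no such gap and no dyes were swapped.

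The fall of the ratio along the 8 sub-grid rows of replicate 1 could come from which genes the rows hold. The same genes would then show it on the other arrays, but replicate 1 minus the mean of replicates 2 and 3, gene by gene, still had row medians spanning 1.04. Sub-grid rows held 15.6% of the variance on replicate 1, 4.19% on replicate 2 and 3.39% on replicate 3, and sub-grids as such held 16.8%, 8.83% and 14.7%. A cause on the array itself stays open, and no biological explanation was tested.

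Exchanging the channels of 1 array gave at most 0 features past the threshold against the real 299, so 1 of 4 splits gave as many, and 4 splits are too few for a share under 0.05.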
